A study of Mus musculus with 19 samples.

How the data were processed

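The series measured pineal tissue of mice at 3 ages with 3 assays. RNA-seq was done on 3 libraries per age, ATAC-seq, which marks accessible chromatin, on 2 per age, and ChIP-seq for H3K27ac, a histone mark of active promoters and enhancers, on 2 libraries at P49 and 2 at P90. Ages were taken from the sample titles. Whether the RNA replicates of an age all came from separate animals is not given in the sources used here, so p-values between ages measure only the spread between these samples, which may be technical in part. Libraries of an age differed in sex-linked transcripts, so they were not all from 1 animal. The labels call the ATAC-seq libraries biological duplicates.

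Per the file headers, the authors counted RNA-seq fragments with featureCounts 2.0.1 on the GENCODE M25 annotation of the mouse build mm10, over whole gene bodies (exons and introns), with strand, for pairs with both ends mapped, and without fragments that hit several genes or aligned several times. The values are raw counts per gene and library. Genes that overlap on the same strand or share sequence with close copies (Hbb-bs and Hbb-bt, the class I and II major histocompatibility genes, Hspa1a and Hspa1b) therefore lost shared fragments, and their levels are uncertain. HISAT2 2.1.0, Bowtie2 2.3.4.1, deepTools 3.5.0, FastQC 0.11.8 and MACS2 2.2.7.1 are named in the submitters' processing notes, without their settings. The authors deposited 1 peak list per ATAC-seq and ChIP-seq library in the MACS2 format, so peaks were called per library. In these deposited lists each peak has a fold enrichment (a ratio over the caller's background), a −log10 p and −log10 q, and an integer score. These values are the authors' and were used only to describe, rank or filter peaks within a list. The score was not used. The filter applied to the lists, the use of an input control and the number of reads behind them are not given in the sources used here, so the depth of the peak lists is unknown.

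The count table holds 55401 gene IDs and 9 library columns, with 0 other columns of values. Column names carry the age and a running number from 1 to 9, which is not the replicate number of the titles, so libraries are called here by age and running number (P10 library 1 to P90 library 9). IDs were paired with symbols by the full ID (54349) and otherwise by the ID without its version (792), and 260 had no symbol. The match by full ID was run first, and its results had been seen before the second step was added, because it left out members of the lists described next. Counts between libraries of an age differed by far more than sampling noise (dispersion index 16.4 to 149, where sampling alone gives about 1), so no library was counted as a duplicate.

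Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM factors, and the quasi-likelihood F test with robust dispersion over all 9 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene past it is said to have risen, fallen or been called. Fold changes are log2 values with a standard error (SE), the absolute log2 fold change divided by the square root of the test's F. The SE rests on the spread over all 9 libraries and not on that of the compared ages alone. For P90 against P49 it thus also draws on the P10 libraries, which were closer to each other. Levels are library-scaled counts in CPM (edgeR's unit) with TMM factors. For the text, the 10 genes with the largest rise and the 10 with the largest fall per comparison were taken among called genes with a mean of at least 5 CPM at the higher age and groups that did not overlap, passing over predicted, ribosomal, histone and immunoglobulin segment genes. To these came up to 4 called members and 1 uncalled member of each fixed list, and 11 genes always reported (Ccnd1, Trp53, Rbp3, Crx, Otx2, Aanat, Asmt, Tph1, Mki67, Mycn and Myc). The 33 lists of genes (pathways, and markers of the cell types that pineal samples could hold), the named-gene rule, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, and adjusted over the 33 lists of a comparison. Of the 634 list members, 633 were in the table. Some genes that the rule names are not reported here.

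Peaks of all libraries of an assay were merged into union regions with a minimum overlap of 1 bp. A region counted as present at an age when both libraries had a peak in it, and as gained or lost when both libraries of 1 age and neither of the other had one. With 2 libraries against 2, no exact test can give a p below 0.333, so gains and losses are counts without a test. The transcription start site (TSS) is the gene's 5′ end in the count table. Regions within 1 kb of a TSS are said to lie at it. Whether called genes had a gained or lost region within 50 kb of their TSS more often than tested genes that were not called was tested with two-sided Fisher exact tests over genes, which are not independent replicates, adjusted over the 12 ATAC and 4 H3K27ac tests. Per chromosome, the median over genes with a mean of at least 5 CPM of log2(CPM + 0.5) minus the mean of the P10 libraries (for a P10 library, of the other 2) was taken after removing the median over all autosomal genes, and compared with 10000 shuffles of genes over chromosomes. All coordinates are mm10.

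On simulated counts with the real means and library sizes, 100 genes changed 2-fold were recovered at 13%, 13% and 18% and 100 changed 4-fold at 69%, 65% and 60% for P49 against P10, P90 against P49 and P90 against P10, among 17671 genes, with 2.35%, 4.49% and 3.53% false calls. A gene that was not called may thus still have changed. Of the 33 simulated lists, 1 was shifted and 1 called in each comparison. The simulated libraries of all ages shared 1 spread per gene, and genes were drawn independently. Real libraries were closer to each other at P10 (dispersion index 16.44 to 35.15) than at P49 and P90 (72.57 to 149.4). The simulated rates of false calls may therefore not hold for the real genes and lists. The merging of peaks and the chromosome medians were also tested on simulated data. Alternatives were other scalings (RLE factors, library totals), filters and tests (DESeq2 1.42.0), a minimum fold, stricter or fewer peaks, peak summits, other windows, and leaving out each library. The alternatives added after the data had been seen are P90 without libraries 7 and 9 (library 8 alone is left at this age, and the lone sample is assumed to vary like the other groups), a brain marker score as a covariate (the mean log CPM of the lists of brain neurons and oligodendrocytes), autosomal genes alone, symbols by full ID alone, peaks covering most of a region, and tests stratified by chromosome. Transcription factor motifs in ATAC regions had been planned and were not analysed here because no genome sequence was used. Calculations on peaks and chromosomes used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.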

Results

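Pineal tissue was studied in mice that carry a Cyclin D1 transgene under the Irbp promoter, which is active in photoreceptors and pinealocytes, and that lack p53. These mice develop pineoblastoma, a malignant tumour of the pineal gland, and the ages stand for a proliferating stage (P10), a premalignant stage (P49) and a tumour stage (about P90). RNA-seq covered 9 libraries, 3 per age, with 18979972 (P10 library 3) to 25760877 (P10 library 1) counted fragments per library. The totals of the others were 21314465 for P10 library 2, 23880713, 23942984 and 21146012 for P49 libraries 4 to 6, and 20857141, 20720114 and 22003409 for P90 libraries 7 to 9. ATAC-seq covered 6 libraries and H3K27ac ChIP-seq 4. Trp53 transcripts were counted at 13.6 to 21.1 CPM over the 9 libraries. Counts over the gene body do not show whether they hold the deleted part, and no mice with p53 were analysed here. Ccnd1 stood at 17.7 CPM at P10, 24.9 at P49 and 21.6 at P90 and was not called in any comparison. Whether transcripts of the transgene are counted in this gene is not given in the sources used here. The first principal component of the RNA libraries held 43.8% of the variance and the second 19.9%. Libraries differed in sex-linked transcripts: Xist was at 227, 299 and 512 CPM in P10 library 1, P49 library 5 and P90 library 9 and below 10 CPM in the others, and Ddx3y, on the Y chromosome, was below 0.1 CPM in those libraries and in P90 library 8. The list of 5 sex-linked genes was not called in any comparison (camera adjusted p = 0.976, 0.608 and 0.765 for P49 against P10, P90 against P49 and P90 against P10). Its median log2 fold changes were 0.0985, −2.99 and −2.71. The list holds Xist and genes of the Y chromosome, which move in opposite directions with sex. The test therefore cannot show whether the ages differed in sex.

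The comparison of P49 with P10 asks what changes between proliferating and premalignant tissue. Single genes of melatonin synthesis, phototransduction and the circadian clock rose. Asmt, which encodes the last enzyme of melatonin synthesis, rose from 2.63 to 28.6 CPM (log2 fold change 3.44 ± 0.71 SE, n = 3 libraries per age). Adra1a, an adrenergic receptor of the nerve input to the gland, rose by 2.75 ± 0.39. All fold changes of expression have this n except where libraries are left out, and their SE comes from the fit over all 9 libraries. Among 32 genes of phototransduction, which pinealocytes share with photoreceptors, 5 rose and none fell (8 and none when adjusted over the list alone): Opn1sw, a cone opsin, by 3.82 ± 0.74, Arr3, cone arrestin, by 3.02, Aipl1, a chaperone of the phosphodiesterase, by 2.35 ± 0.27 and Gnat2, cone transducin, by 1.87 ± 0.32. The whole list lay above other genes (median log2 fold change 0.65, camera adjusted p = 0.0064), with adjusted p = 0.634 with an estimated correlation and 0.141 without P49 library 6. Of 15 melatonin and adrenergic genes 2 rose (4 when adjusted over the list alone), with camera adjusted p = 0.108 (0.0441 with the brain marker score). Tph1, the first enzyme of the pathway, had a log2 fold change of 0.05 ± 0.44 at 2051 CPM at P49. Of 20 pineal and photoreceptor transcription factors 2 rose, Six6 by 6.24 ± 0.81 and Thrb by 1.52 ± 0.37 on chromosome 14, whose median shift was −0.02 to 0.18 in the P49 libraries (3 up and 5 down when adjusted over the list alone, camera adjusted p = 0.447), while Crx, the regulator of photoreceptor and pineal genes, stood at −0.06 ± 0.23 and Otx2 at −0.44 ± 0.15. Of 16 circadian clock genes 4 rose, Nr1d1 by 2.72 ± 0.43, Bhlhe41 by 2.43, Dbp by 2.17 ± 0.40 and Cry2 by 1.01 (camera adjusted p = 0.014, adjusted p = 0.64 with an estimated correlation, 0.0521 without P49 library 4). The hour of collection is not given in the sources used here.

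Genes of dividing cells lay lower at P49 as groups, with few single calls. Of 30 cell cycle genes none passed the edgeR test over all genes or adjusted over the list alone, while 10 were lower at an unadjusted p below 0.05 and 3 with DESeq2. Their median log2 fold change was −0.80 (camera adjusted p = 2.21e-08). Mki67, a marker of cycling cells, had 1024 CPM at P10 and 493 at P49 (−1.05 ± 0.37, adjusted p = 0.119). The list of 29 replication genes had a median of −0.57 (camera adjusted p = 2.86e-06) with 1 member down, the polymerase gene Pola1 (−0.93 ± 0.21), and that of 21 DNA repair genes a median of −0.50 (2.39e-06) with Bard1 (−1.26 ± 0.25) and Brca2 (−0.77 ± 0.19) down (1 and 3 down when adjusted over the lists alone). P49 library 4 held 222 CPM of Mki67 against 657 and 599 in libraries 5 and 6. It also stood apart from these on the second principal component (−80.9 against −34.5 and −42.0) and in the share of mitochondrial counts, which was 3.44%, 1.85% and 1.98% in P49 libraries 4 to 6, 0.985% to 1.13% at P10 and 1.43% to 2.28% at P90. Of 17 MYC family and G1 regulators 2 fell, Mycl by −2.48 ± 0.59 and the Cdk inhibitor Cdkn2c by −0.89 ± 0.21 (1 up and 5 down when adjusted over the list alone), and the list had camera adjusted p = 0.0451, which was 0.0574 without P10 library 3, 0.0633 without P49 library 4 and 0.0734 without P49 library 6. It was also lost with library totals (0.0617), the brain marker score (0.0724) and symbols by full ID alone (0.0714). Of 10 SHH pathway genes 2 fell, the transcription factors Gli3 (−1.87 ± 0.44) and Gli2 (−1.25 ± 0.20), with camera adjusted p = 0.0032. The 30 chromatin repressors had no member called by edgeR (7 lower at an unadjusted p below 0.05, 4 with DESeq2) and a median of −0.22 (camera adjusted p = 0.0123, 0.0521 without P49 library 4). With an estimated correlation each of these 6 lists had adjusted p = 0.634. Of 27 neural progenitor genes Igf2bp2 (−1.76) and Sox4 (−1.29 ± 0.23) fell. The list had a median of 0.26 and a mean of 0.25, camera put it in the lower direction, and it was not called (adjusted p = 0.835).

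Immune and astrocyte transcripts were higher at P49. Of 16 antigen presentation genes 10 rose and none fell (13 when adjusted over the list alone), with the class II genes H2-Eb1 (3.88 ± 0.60) and H2-Aa (3.82) and the invariant chain gene Cd74 (3.62 ± 0.57, from 13.1 to 160 CPM) first. The list had camera adjusted p = 1.07e-09. Of 25 interferon response genes 7 rose (9 when adjusted over the list alone; camera adjusted p = 1.09e-08), among them Ifi44 (2.99), Cxcl10 (2.66) and Ifit3 (2.11 ± 0.40). Microglia and macrophage markers moved with them: 7 of 17 rose (9 up and 1 down when adjusted over the list alone; camera adjusted p = 3.43e-05), such as Lyz2 (2.57) and the complement genes C1qb (1.71 ± 0.31) and C1qc (1.52 ± 0.23). Of 15 astrocyte markers 5 rose, Gfap by 2.95 ± 0.71, Aqp4 by 2.80, Slc1a3 by 2.44 and Clu by 2.22 ± 0.30 (7 when adjusted over the list alone; camera adjusted p = 0.000215). Of 29 genes of neurons and synapses 3 rose, Slc17a7 (1.98), Nefh (1.92) and Rab3a (0.90), with camera adjusted p = 0.0373 (0.0622 without P49 library 6 and 0.136 with the brain marker score). Of 7 erythroid genes 2 fell, among them Slc4a1 by −4.03 (2 when adjusted over the list alone; camera adjusted p = 0.00249), and of 17 endothelial genes Vwf fell by −1.08 ± 0.21 (camera adjusted p = 0.014, 0.0987 without P49 library 5). With an estimated correlation all of these 7 lists had adjusted p = 0.634.

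Among called genes with at least 5 CPM and groups that did not overlap, passing over predicted, ribosomal and immunoglobulin genes, the largest rises at P49 were those of Tc2n, from 11.9 to 661 CPM (5.79 ± 1.12), Glycam1, which encodes a mucin-like glycoprotein, from 0.233 to 10.4 CPM (5.46 ± 0.80), and Syt6, a synaptotagmin, from 1.93 to 77.0 CPM (5.32 ± 0.68). The largest falls by the same rule were Otoa, from 27.1 to 1.39 CPM (−4.28 ± 0.61), Ripply1 (−4.08) and Slc4a1, and the imprinted RNA H19 fell from 114 to 13.3 CPM. Tc2n and Six6 lie on chromosome 12, whose genes had median shifts of 0.15, 0.60 and 0.35 (log2) in P49 libraries 4 to 6. In all, 741 genes rose and 383 fell among 17671 tested (1124 called, 819 of them at least 2-fold; 4487 at an unadjusted p below 0.05), and 6982 genes had groups that did not overlap, where chance gives 10%. The edgeR count rested on few libraries: it was 14, 29 and 2 without P10 library 1, 2 or 3 and 252 without P49 library 4, while DESeq2 called 2618, of which 1118 were shared.

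**Figure D1:**
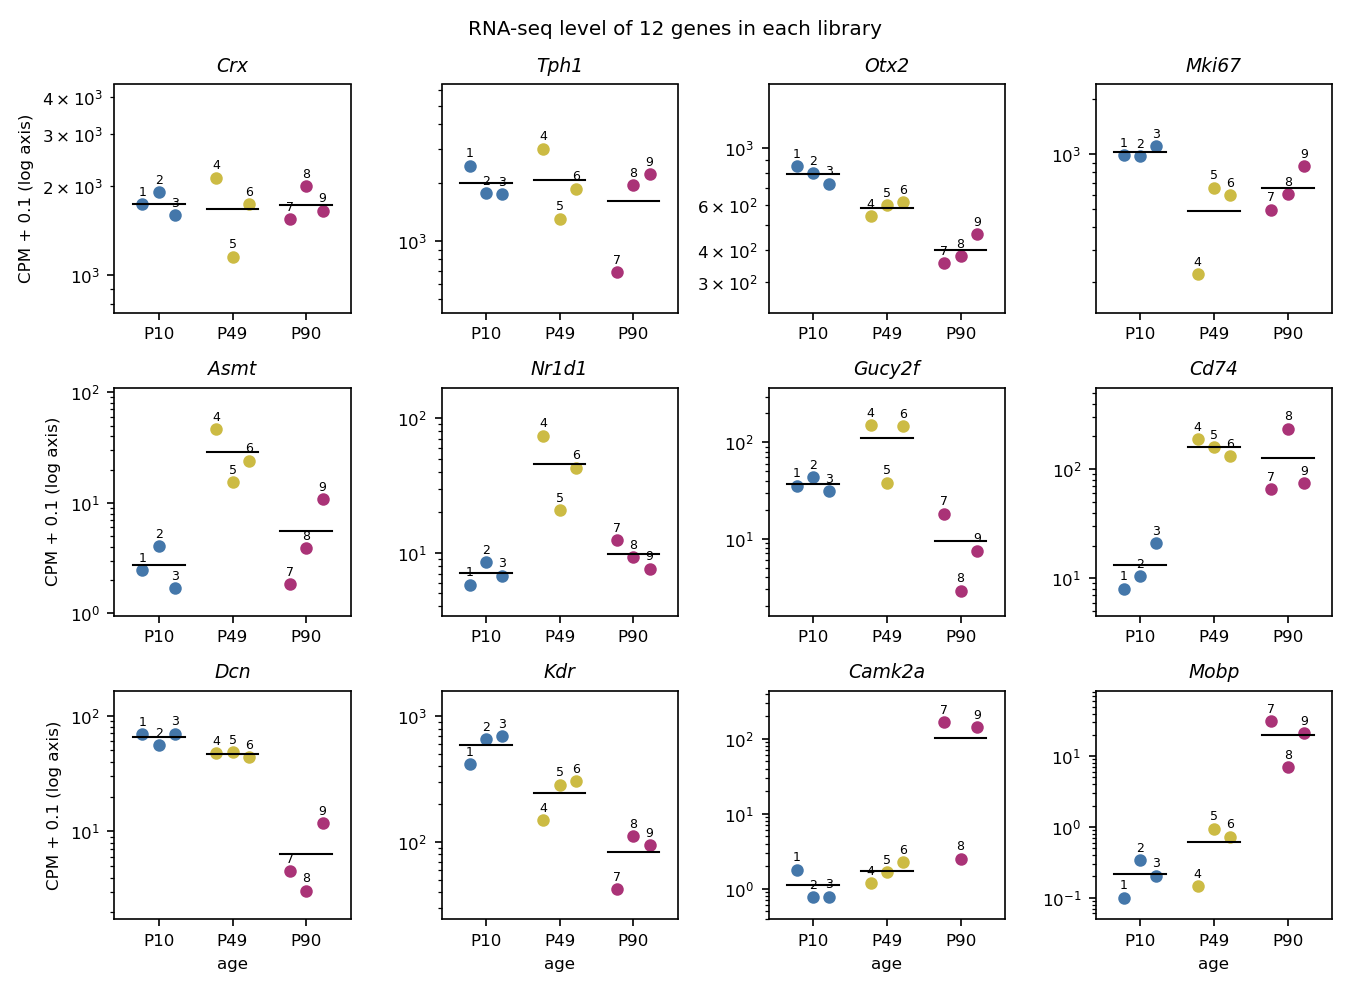
RNA-seq levels of 12 genes in CPM plus 0.1 on log axes whose range differs between panels, against age; each point is a library with its running number and each bar the mean of 3 libraries of an age. Crx lay between 1156 and 2138 CPM, Asmt and Nr1d1 had their highest mean at P49, and Camk2a was high in P90 libraries 7 and 9 alone.

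The comparison of P90 with P49 asks what sets tumour tissue apart from premalignant tissue. Members of the pineal and photoreceptor lists fell. Of the 32 phototransduction genes 5 fell and none rose (1 up and 11 down when adjusted over the list alone), among them Opn1sw by −6.03 ± 0.88, Gucy2f, a photoreceptor guanylate cyclase, from 112 to 9.41 CPM (−3.57 ± 0.71), the channel subunit Cngb3 (−2.40 ± 0.51) and the phosphodiesterase subunit Pde6b (−2.02 ± 0.42). The list had a median of −0.95 (camera adjusted p = 0.00156, adjusted p = 0.721 with an estimated correlation). Ddc, the second enzyme of the melatonin pathway, fell by −2.33 ± 0.49, Prkar2b, a regulatory subunit of protein kinase A, by −2.58 ± 0.48 and Adra1a by −2.56 ± 0.38 (3 of 15 in the list, 4 when adjusted over the list alone, camera adjusted p = 0.0678). Tph1 stood at −0.35 ± 0.44 and Asmt at −2.40 ± 0.68 (adjusted p = 0.063). Of the 20 transcription factors Neurod4 fell from 728 to 82.9 CPM (−3.13 ± 0.49), Lhx4 by −2.05 ± 0.47 and Thrb by −1.81 ± 0.37, and Mef2c rose by 3.46 ± 0.83, which was −1.31 with the brain marker score and −0.18 without libraries 7 and 9 (4 up and 7 down when adjusted over the list alone, camera adjusted p = 0.158). Crx stood at 0.05 ± 0.23 and Otx2 at −0.56 ± 0.15 (adjusted p = 0.057). Otx2 and Thrb lie on chromosome 14, whose genes had median shifts of −0.33, −0.29 and −0.21 in P90 libraries 7 to 9. Of 16 clock genes 4 fell: Dbp by −2.29 ± 0.40, Nr1d1 by −2.24 ± 0.43 and Bhlhe41 by −2.01, which had risen at P49, and Nr1d2 by −1.09 (1 up and 6 down when adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.771 with an estimated correlation, 0.0824 without P90 library 8).

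Transcripts of other cell types moved at the same step, in both directions. Of 16 oligodendrocyte markers 11 rose and none fell (12 when adjusted over the list alone): Olig2 by 5.72, Mobp by 5.25 ± 0.95, Olig1 by 4.79 and Mog by 4.65 (median 3.36, camera adjusted p = 2.47e-08, adjusted p = 0.721 with an estimated correlation). Of 14 markers of neurons from neighbouring brain regions 4 rose (8 up and 2 down when adjusted over the list alone), such as the kinase gene Camk2a (6.01 ± 1.25) and the peptide genes Sst (5.16) and Npy (4.95), with a median of 3.12 (camera adjusted p = 0.00569, adjusted p = 0.721 with an estimated correlation). Tac2 was at 0 CPM in the libraries of P10 and P49 and at a mean of 2.09 at P90. The P90 libraries differed: Camk2a was at 166 and 143 CPM in libraries 7 and 9, at 2.44 in library 8 and at 1.10 to 2.17 at P49. Sst was at 20.7, 33.3 and 9.29 CPM in libraries 7 to 9, highest in library 8, as was Tac2 (4.19). Mobp was at 31.2, 6.92 and 21.1 CPM in libraries 7 to 9 and at most 0.849 at P49. Among the largest rises by the rule used for P49 were likewise neuronal genes, Ddn from 0.24 to 74.0 CPM (8.25 ± 1.40), Nrgn (7.72 ± 1.38), Icam5 (6.95) and Hpcal4 (6.90). With the brain marker score as a covariate Camk2a had −1.36 and Hpcal4 −1.56. Of the 29 neuron and synapse genes Nefl (4.40), Nefm (3.15) and Stx1a (2.66) rose, with −0.29 each for Nefl and Stx1a under that score (4 up and 2 down, 10 and 4 when adjusted over the list alone, camera adjusted p = 0.0689). Without libraries 7 and 9 the list of brain neurons had camera adjusted p = 0.115. That alternative leaves P90 with library 8 alone wherever it is given, and the lone sample is assumed to vary like the other groups.

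Fibroblast and meningeal genes fell, 5 of 15 with none up (11 down when adjusted over the list alone): Aldh1a2, an enzyme of retinoic acid synthesis, by −3.23 ± 0.47, the proteoglycan genes Dcn (from 46.3 to 6.34 CPM, −2.86 ± 0.43) and Lum (−2.40), and the transporter Slc6a13 (−2.77). The list had camera adjusted p = 2.66e-07 (adjusted p = 0.721 with an estimated correlation). Among the largest falls by the same rule were Wnt2b (−5.11 ± 0.67), the heparanase homologue Hpse2 (−4.92 ± 0.35) and Krt18, an epithelial keratin, from 128 to 5.60 CPM (−4.51 ± 0.79). Of 27 neural progenitor genes Zic1 (−1.97 ± 0.29), Prom1 (−1.36 ± 0.33) and Notch2 (−1.08) fell (4 when adjusted over the list alone; camera adjusted p = 0.0164, adjusted p = 0.721 with an estimated correlation, 0.0609 without P49 library 5, 0.0664 without P49 library 6 and 0.162 without P90 library 8). Of the 10 SHH pathway genes Gas1, a co-receptor, fell by −2.25 ± 0.27 and the receptor gene Ptch1 by −0.95 ± 0.21 (5 when adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.721 with an estimated correlation). Of 17 G1 regulators Ccnd2 fell by −1.92 ± 0.33 (camera adjusted p = 0.941). Of 30 chromatin repressors 2 rose, Bcl11a (3.89 ± 0.70) and Hdac9 (2.55), both also abundant in brain, and 4 fell, among them Cbx5, heterochromatin protein 1 alpha (−0.92 ± 0.14), and the Polycomb gene Cbx7 (−0.80 ± 0.19), with camera adjusted p = 0.762.

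Of 20 immediate early and heat shock genes 4 rose and 1 fell (9 up and 1 down when adjusted over the list alone): Egr3 (4.50, and −0.49 with the brain marker score), Arc (3.15), Nr4a1 (1.70) and Fos (1.61 ± 0.41, on chromosome 12) rose (camera adjusted p = 0.00443, adjusted p = 0.721 with an estimated correlation). Of 25 interferon genes Ifi27 rose by 1.85 (camera adjusted p = 0.00265, adjusted p = 0.771 with an estimated correlation). Ifi27 also lies on chromosome 12, whose median shift was 0.37 to 0.62 in the P90 libraries. Cell cycle and replication genes had 0 members called by edgeR over all genes or adjusted over the list alone, 0 at an unadjusted p below 0.05 and 0 with DESeq2, and medians of 0.33 and 0.32 (camera adjusted p = 0.00443 and 0.00728, each with adjusted p = 0.776 with an estimated correlation). Both calls depended on P49 library 4, without which the direction turned (camera adjusted p = 0.898 and 0.904). Without P90 library 9 they had 0.0866 and 0.0526, and replication 0.21 without P90 library 8. DNA repair genes had a median of 0.38 and none called by edgeR, with 3 higher at an unadjusted p below 0.05 and 2 with DESeq2 (camera adjusted p = 0.0238, adjusted p = 0.771 with an estimated correlation, 0.588 without P49 library 4, 0.167 without P90 library 8 and 0.0866 without P90 library 9). Mki67 stood at 0.41 ± 0.37, Mycn at 0.23 and Myc at 1.05 ± 0.45, and none of these was called. With the brain marker score as a covariate the lists of phototransduction (0.476), circadian clock (0.463), SHH pathway (0.268), interferon (0.254), replication (0.332) and DNA repair genes (0.477) were no longer called at P90 against P49. That score was 2.6, 0.356 and 2.18 in P90 libraries 7 to 9 and at most −0.0869 at the earlier ages. It thus overlaps with age and cannot tell brain tissue from a change with age. Leaving out libraries 7 and 9 kept the direction of each of these lists. Without libraries 7 and 9 the cell cycle list had 0.115 and the repair list 0.0646.

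In all, 571 genes rose and 778 fell (1349 called, 1051 at least 2-fold; 4711 at an unadjusted p below 0.05), and 4280 of 17671 had groups that did not overlap, where chance gives 10%. The balance turned without P90 library 8 (1325 rose and 977 fell), without libraries 7 and 9 (470 and 370) and with the brain marker score (35 and 21), and with library totals it was 595 and 629. With library totals as the scaling, the median over all genes was 0.105 (log2) in place of 0.03. The edgeR count was 204 without P49 library 4, 349 without library 6, 713, 2302 and 617 without P90 library 7, 8 or 9, and 840 without both 7 and 9, of which 327 were shared. It was 35 when P10 libraries were left out of the estimate of spread, 56 with the brain marker score as a covariate, and 3070 with DESeq2. Of the named genes called at this step, 84 missed the threshold and 4 kept it when P10 libraries were left out.

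The comparison of P90 with P10 spans both steps. Interferon and antigen presentation genes were higher at P90: 16 of 25 interferon genes rose (19 when adjusted over the list alone, none down), with Ifi27 by 3.70 ± 0.44 and Irf7, a regulator of the response, by 3.12, and 13 of 16 antigen presentation genes (16 when adjusted over the list alone), with H2-Eb1 by 3.51 ± 0.59 and Cd74 by 3.27. Their camera adjusted p was 5.94e-11 and 2.99e-10, and adjusted p = 0.394 with an estimated correlation for both. Microglia markers rose in 12 of 17 (14 when adjusted over the list alone), C1qa by 2.04 ± 0.20, and 2 fell, one of them Cd163 (−2.30), a marker of border macrophages. The list had camera adjusted p = 2.2e-05 and adjusted p = 0.394 with an estimated correlation. Of 15 astrocyte markers 9 rose (10 when adjusted over the list alone), Gfap by 4.63 ± 0.76 and Slc1a3 by 4.39 (camera adjusted p = 0.000531, adjusted p = 0.479 with an estimated correlation, 0.0678 without libraries 7 and 9, 0.215 with the brain marker score). Markers of oligodendrocytes (12 up and 1 down of 16, camera adjusted p = 1.28e-05, adjusted p = 0.447 with an estimated correlation), of brain neurons (7 up of 14, 9 up and 1 down when adjusted over the list alone, 0.0348, with adjusted p = 0.394 with an estimated correlation and 0.0987 without P90 library 7) and of neurons and synapses (13 up and 1 down of 29, 16 and 2 when adjusted over the list alone, 0.00118, with adjusted p = 0.394 with an estimated correlation) rose as well. Without libraries 7 and 9 the neuron and synapse list had camera adjusted p = 0.24 and that of brain neurons 0.127, and with library totals the latter had 0.0557. With the brain marker score the oligodendrocyte list had 0.0999 and the neuron and synapse list 0.869.

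The lists of SHH pathway and fibroblast genes were lower at P90 than at P10. Of 10 SHH pathway genes 8 fell and none rose: Gas1 by −2.90 ± 0.28, Sfrp1 by −2.69, Gli3 by −2.12 and Smo by −1.48 (camera adjusted p = 1.98e-05, adjusted p = 0.376 with an estimated correlation). Fibroblast genes fell in 8 of 15 (11 when adjusted over the list alone), Dcn by −3.35 and Ogn by −3.14 (camera adjusted p = 4.12e-06, adjusted p = 0.394 with an estimated correlation). Of 27 neural progenitor genes 6 fell, such as Zic1 (−3.05 ± 0.30), Msx1 (−2.97), Igf2bp2 (−2.54) and Prom1, from 981 to 186 CPM (−2.40 ± 0.35), and 1 rose (camera adjusted p = 0.0502, 0.000201 with the brain marker score and 0.00204 without libraries 7 and 9, with library 8 alone). Kdr, the VEGF receptor of endothelium, fell from 590 to 82.6 CPM (−2.84 ± 0.42), while the endothelial genes Cldn5 and Robo4 rose by 1.94 and 0.99, and the list of 17 was not called (3 up and 2 down, camera adjusted p = 0.765). Otx2 fell from 792 to 398 CPM (−0.99 ± 0.15, adjusted p = 0.0047), on chromosome 14 with its shifts of −0.33 to −0.21 at P90. Crx (−0.01), Tph1 (−0.30), Asmt (1.04) and Aanat (−1.15) were not called. Of 20 pineal transcription factors 3 rose, with Lhx2 by 3.41, and 5 fell, with Neurod4 by −2.65 (camera adjusted p = 0.0721). Of 32 phototransduction genes 6 rose, with Pde6h by 4.58 and Aipl1 by 2.62 ± 0.27, and 3 fell (6 and 3 when adjusted over the list alone, camera adjusted p = 0.579).

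Single regulators of the cell cycle changed. Cdkn2a, a tumour suppressor locus that restrains Cdk4, Cdk6 and Mdm2, rose from 3.93 to 25.1 CPM (2.68 ± 0.56), Ccnd2 fell from 119 to 19.9 CPM (−2.58 ± 0.34), Mycl by −2.22 and Cdkn2c by −1.04. The list of 17 regulators had camera adjusted p = 0.12 (1 up and 6 down when adjusted over the list alone). None of 30 cell cycle genes was called by edgeR over all genes or adjusted over the list alone (2 lower at an unadjusted p below 0.05, 0 with DESeq2), and their median was −0.47 (camera adjusted p = 0.0193, adjusted p = 0.83 with an estimated correlation, 0.182 without P90 library 7, 0.0877 without libraries 7 and 9). Mki67 (−0.64), Mycn (−0.34) and Myc (0.36) were not called. Replication genes (2 down of 29, among them Tyms by −1.10; 0.0972) and DNA repair genes (5 down of 21, among them Atm by −0.49 and Msh6 by −0.56; 0.0615) were not called as lists. Atm lies on chromosome 9, with median shifts of 0.01, −0.36 and −0.23 in P90 libraries 7 to 9, and Msh6 on chromosome 17, with −0.12, −0.25 and −0.19. Among 22 p53 targets Zmat3 rose by 1.40 ± 0.22 and Bbc3, a cell death gene, by 1.28 and Eda2r fell by −4.21 (3 up, 2 down, camera adjusted p = 0.93; the median of −0.02 and mean of −0.10 were negative and the test positive). Immediate early genes rose in 8 of 20 (9 when adjusted over the list alone), with Egr3 by 5.10, which was −0.42 with the brain marker score (camera adjusted p = 0.0023, adjusted p = 0.394 with an estimated correlation).

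Among the largest changes over both steps by that rule were Cck (8.63 ± 1.32) and Hpcal4 (7.73), which are neuronal transcripts with 1.56 and 1.95 CPM in library 8 and more in libraries 7 and 9, and, downward, Sycp1, a gene of meiotic chromosomes (−7.43 ± 1.54), Slc4a1 (−7.22 ± 1.05), Stk26 (−5.91 ± 0.52), the endothelial gene Esm1 (−5.26 ± 0.73) and Hpse2 (−5.27 ± 0.35). Etnppl was at 0 CPM in the P10 libraries and at a mean of 12.8 at P90. In all, 2065 genes rose and 1423 fell (3488 called, 2441 at least 2-fold; 6263 at an unadjusted p below 0.05), and 7801 of 17671 had groups that did not overlap, where chance gives 10%. The edgeR count was 1289, 1217 and 1319 without P10 library 1, 2 or 3, 2405 without both P90 libraries 7 and 9, and 543 with the brain marker score as a covariate.

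Genes called at both steps numbered 208. Most had risen at P49 and fallen at P90 (135, against 32.6 for independent lists of these sizes), among them Opn1sw, Adra1a (2.75 and −2.56), Dbp (2.17 and −2.29), Nr1d1 (2.72 and −2.24) and Thrb (1.52 and −1.81). Another 31 had fallen and then risen (12.4 for independent lists), such as the myelin gene Mbp (−1.72 and 2.79) and the neuronal calcium sensor Hpca (−3.23 and 3.04). Ifi27 was among 26 that rose at both steps (23.9 for independent lists) and Cpz among 16 that fell at both steps (16.9). Groups simulated without change around the same P49 libraries gave 0 in each class. That simulation held no true change at either step, so it cannot show how much of the excess comes from the shared P49 libraries. Part of the excess may come from them. The total was 3, 6 and 0 without P10 library 1, 2 or 3, 33 and 78 without P49 library 4 or 6, 431 and 119 without P90 library 8 or 9, and 648 with DESeq2.

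ATAC regions were similar in number at P10 and P49 and fewer at P90. Both libraries of an age shared 29308 ATAC regions at P10, 29089 at P49 and 17289 at P90. From P10 to P49 2501 regions were gained and 2694 lost, with 22770 present at both ages. From P49 to P90 1344 were gained and 9602 lost (14304 at both), and from P10 to P90 911 were gained and 8554 lost. The regions that changed lay mostly away from promoters: 7.72% of those gained at P49 and 15.8% of those lost at P90 were at a TSS, against 40.2% of all P49 regions, and 51.7% of those lost at P90 lay inside genes. Promoters were among them: 22 of 32 phototransduction genes had a region at the TSS at P49 and 9 at P90. For the pineal transcription factors it was 15 and 9 of 20, for oxidative phosphorylation genes 19 and 9 of 19, and for microRNA processing genes 11 and 11 of 11. The P90 libraries held fewer peaks (30280 and 23841) than those of P49 (39240 and 39198) or P10 (32724 and 45890). With the 20000 strongest peaks of each library 3326 regions were gained and 3795 lost from P49 to P90, and 2203 and 3170 from P10 to P90. From P10 to P49 1735 were gained and 1600 lost. At q below 1e-05 the gains at P90 were 871 against P49 and 438 against P10.

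With 1 library left at an age, counts grew, since a region then needs only that library. Gains at P49 were 5991 without P10 replicate 2, 8776 without P49 replicate 1 and 7459 without P49 replicate 2, and losses 11331 and 4718 without P10 replicate 1 or 2 and 4968 and 4275 without P49 replicate 1 or 2. From P49 to P90 gains were 2161 and 2165 without P49 replicate 1 or 2 and 4734 and 8799 without P90 replicate 1 or 2, and losses 17458 and 17307 without P49 replicate 1 or 2. From P10 to P90 gains were 1635 without P10 replicate 2 and 3970 and 8137 without P90 replicate 1 or 2, and losses 21725 without P10 replicate 1.

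H3K27ac regions were far more numerous at P90. Both libraries shared 2283 regions at P49 and 30366 at P90, of which 25105 were gained, with 645 lost and 1606 present at both ages. At P90 62.0% of ATAC regions carried the mark, and at P49 7.91%. All 30 cell cycle promoters had it at P90 and 1 at P49. The libraries themselves differed: those of P49 held 6652 and 9731 peaks over 2.86 and 3.67 Mb and shared 40.8% of the smaller set, and those of P90 39000 and 54728 peaks over 47.7 and 57.9 Mb and shared 81.2%. At 6708 promoters that were open at both ages and whose expression was not called and moved by less than 0.5 (log2), 17.2% had a region of both P49 libraries (45.3% of replicate 1 and 23.2% of replicate 2) and 99.7% one of both P90 libraries. Of the regions of P49 replicate 1, 78.7% and 79.2% were shared with P90 replicates 1 and 2, and of those of P49 replicate 2, 28.6% and 28.9%. With the 5000 strongest peaks per library 1594 regions were gained and 412 lost. Gains were 49275 without P90 replicate 1, and losses 6310 and 1161 without P49 replicate 1 or 2, 118 at q below 1e-05 and 350 where peaks had to cover most of the region.

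**Figure D2:**
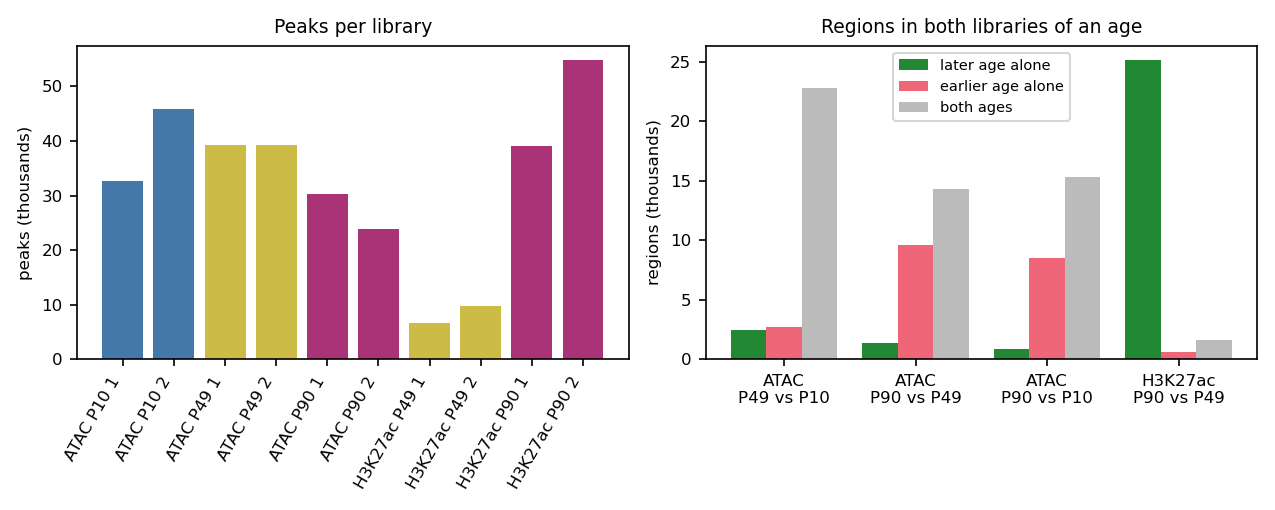
Left, number of peaks in each ATAC-seq and H3K27ac library (axis in units of 1000), coloured by age; right, number of regions (same unit) found in both libraries of the later age alone, of the earlier age alone, or of both ages. Losses exceed gains for ATAC at P90 (9602 against 1344), and H3K27ac regions are mostly of P90 alone (25105).

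In 4 of 12 tests ATAC changes lay near expression changes of the same direction. Of genes that rose at P49, 19.5% (144 of 738) had a gained ATAC region within 50 kb of their TSS, against 10.1% of genes that were not called (odds ratio 2.15, Fisher exact adjusted p = 1.66e-12). Of genes that fell at P90 against P49, 55.1% (429 of 778) had a lost region, against 43.2% (odds ratio 1.62, 95% interval 1.40 to 1.87, Fisher exact adjusted p = 3.81e-10). Genes that fell at P49 had a lost region in 20.1% against 14.1% (odds ratio 1.54, adjusted p = 0.00554), which did not pass with a window of 10 kb (1.36) or 100 kb (1.18), at the TSS alone (1.29) or with the 20000 strongest peaks (1.38). For genes that fell at P90 against P10 the odds ratio was 1.17 (adjusted p = 0.0126), a call that was lost when stratified by chromosome (1.07, adjusted p = 0.425) and within 100 kb (1.06, adjusted p = 0.422). With the 20000 strongest peaks genes that rose at P90 against P10 lay near gained regions more often (1.83, adjusted p = 7.48e-10), and those that fell less often (0.695, adjusted p = 0.0354). These tests were not stratified by chromosome, so they do not separate nearby changes from those of whole chromosomes. In the main test genes that rose at P90 against P10 had 1.37 for gained regions (Fisher exact adjusted p = 0.15). Stratified by chromosome it was 0.938. Genes that rose there lay near lost regions, against the direction, in alternatives: stratified by chromosome (odds ratio 1.19, adjusted p = 0.00223), within 10 kb (1.22, adjusted p = 0.00412) and at least 2-fold (1.17, adjusted p = 0.00772), with 1.03 (adjusted p = 0.568) in the main test. Genes that fell at least 2-fold at P90 against P49 likewise lay near gained regions (1.62, adjusted p = 0.0397). Genes that rose at P90 against P49 had a gained region in 3.85% against 3.09% (odds ratio 1.26, adjusted p = 0.568). With the 20000 strongest peaks they lay near lost regions less often (odds ratio 0.744, Fisher exact adjusted p = 0.015), against 0.982 in the main test. For H3K27ac, 93.2% of genes that rose at P90 had a gained region against 85.5% of those not called (odds ratio 2.32, 1.65 to 3.17, adjusted p = 4.82e-08) and 75.6% of those that fell (0.526, 0.443 to 0.621, adjusted p = 6.66e-12). With the 5000 strongest peaks per library the first turned to an odds ratio of 0.725 (Fisher exact adjusted p = 0.00774). Few H3K27ac regions were found at P49, so most regions present at P90 counted as gained. At the TSS, 82.7% of genes that rose had a region of both P90 libraries, against 77.7% of those not called and 65.0% of those that fell. The H3K27ac tests therefore cannot tell a gain of the mark from its presence at P90.

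The Otx2 locus (chromosome 14, 48657677 to 48673819, minus strand; Otx2 is a homeobox regulator of pineal and photoreceptor fate) had no ATAC peak at P90. It was singled out from the genes always reported after the peaks had been seen. Within 50 kb of its TSS the P10 libraries had 6 and 10 peaks, the P49 libraries 9 and 12, and the P90 libraries 0 and 0. Of 8 regions lost from P49 to P90 one covered the promoter (48673431 to 48675546) and 1 lay upstream (48709516 to 48710192). The others lay within or downstream of the gene. H3K27ac stayed at the TSS in every library, with 4 and 6 peaks within 50 kb at P49 and 4 and 11 at P90. Tph1 had 8 and 8, 9 and 10, and 4 and 4 ATAC peaks at the 3 ages and Rbp3 4 and 5, 5 and 5, and 2 and 2, while Crx kept 8 and 9, 8 and 9, and 8 and 7, and Mycn 4 and 5, 5 and 5, and 4 and 4. Syt6 had 1 and 1, 2 and 2, and 0 and 0. The P90 ATAC libraries held fewer peaks in all. In P90 replicates 1 and 2 the share of peaks on chromosome 14 was 0.849 and 0.549 times that at P10. For chromosome 7, which holds Crx, it was 1.09 and 0.801 times, and for chromosome 12, which holds Mycn, 2.2 and 1.8 times. Whether the loss is particular to the Otx2 locus was not tested.

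**Figure D3:**
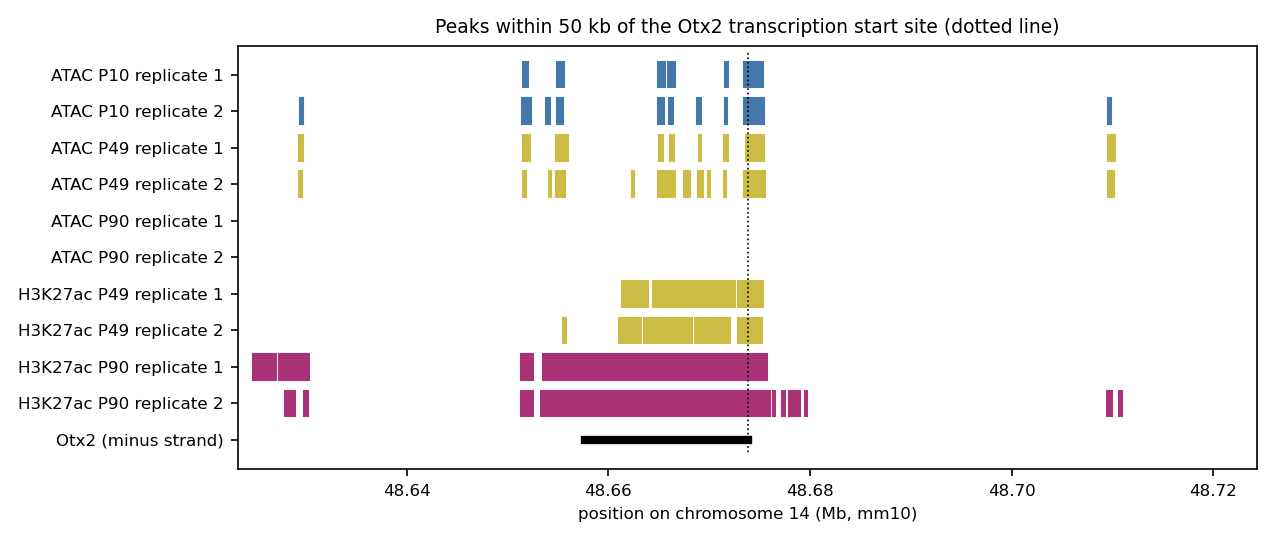
Map of peaks within 50 kb of the Otx2 TSS (dotted line) on chromosome 14 in Mb of mm10, with 1 line per ATAC-seq and H3K27ac library coloured by age and the gene body in black. The P90 ATAC libraries have 0 peaks here, while each H3K27ac library has a peak over the TSS.

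Levels also shifted by chromosome. Genes of chromosome 12 had median shifts of 0.15, 0.60 and 0.35 (log2, against P10) in P49 libraries 4 to 6 and of 0.37, 0.55 and 0.62 in P90 libraries 7 to 9. These exceeded the shuffled genes in each library (permutation p = 1e-04, the smallest that the shuffles can give, except 0.0002 in library 4). Of its genes 219 rose and 20 fell at P90 against P10 (Fisher exact adjusted p = 3.76e-29 over 60 tests). Most other chromosomes were also unbalanced in that comparison, such as chromosome 8 (144 rose, 18 fell), 11 (204, 46), 2 (212, 67) and 4 (86, 137). Only chromosomes 3, 5, 6, 15, 16 and 18 did not pass these tests. On the X chromosome, which holds Pola1 and Ripply1, 11 rose and 39 fell at P49 against P10 (Fisher exact adjusted p = 7.23e-10). On chromosome 14, which holds Otx2, Thrb and Rbp3, 18 genes rose and 105 fell at P90 against P49 (Fisher exact adjusted p = 6.59e-11). Nr1d2 also lies there. Ptch1, Gli3, Gas1 and Sox4 lie on chromosome 13, with shifts of −0.18, −0.24 and −0.12 in P49 libraries 4 to 6. In P90 libraries 7 to 9 its shifts were −0.50, −0.41 and −0.27, and those of chromosome 4, which holds Cdkn2c, −0.33, −0.13 and −0.24.

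**Figure D4:**
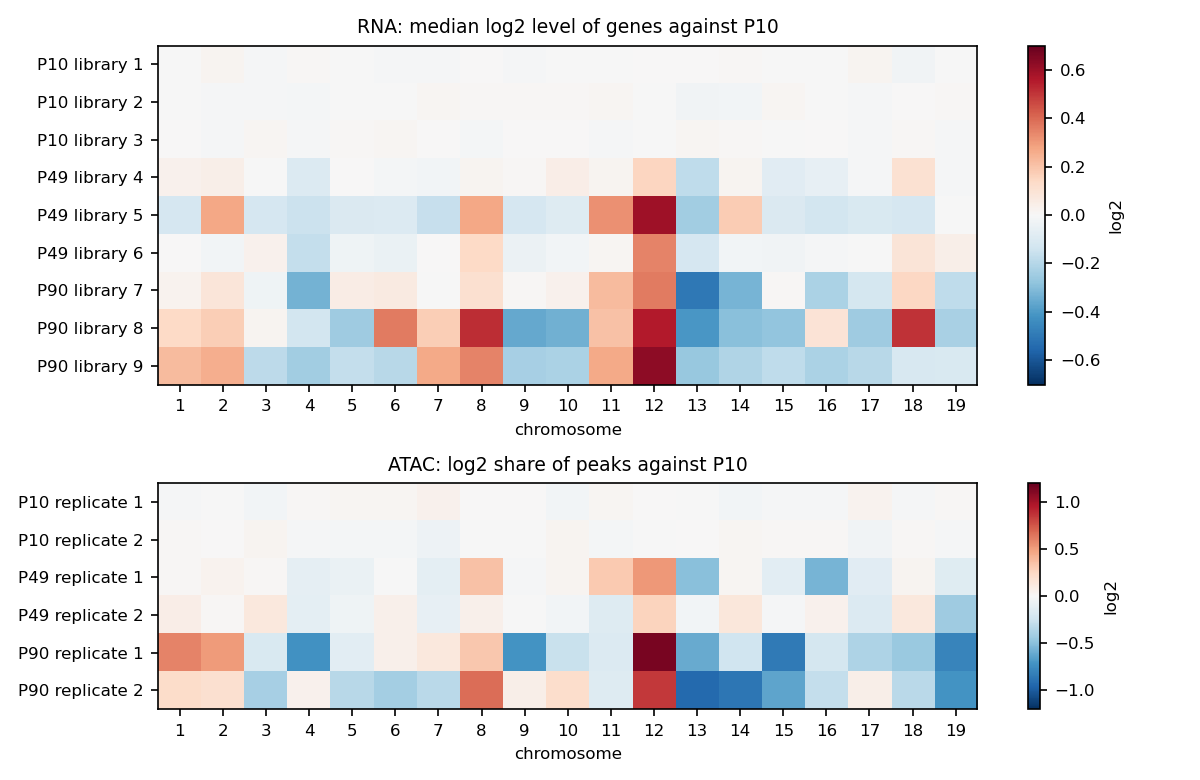
Heat maps of 19 autosomes (columns) by library (lines): above, the median log2 level of genes against P10 in the 9 RNA-seq libraries; below, the log2 share of peaks against P10 in the 6 ATAC-seq libraries. Chromosome 12 is higher after P10, with up to 0.62 in RNA and 1.14 in ATAC.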

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

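The alternatives without P90 libraries 7 and 9, with the brain marker score, on autosomal genes, with symbols by full ID, with peaks covering most of a region and with tests stratified by chromosome were chosen after the results had been seen. The others had been planned. Without libraries 7 and 9 P90 keeps library 8 alone, and the lone sample is assumed to vary like the other groups. No paired analysis was possible because the columns of the count table carry a running number and not the replicate number of the titles. Motif shares in ATAC regions were not run for want of a genome sequence, and the planned minimum overlap of peaks with union regions was void because these contain every peak. For single named genes 2902 values under alternatives kept their direction and side of the threshold, 1151 missed it and 23 reversed. For called lists it was 377, 139 and 9, and for odds ratios 35, 6 and 1. Named genes at P90 against P49 depended most on the fit. With the 6 libraries of these ages alone 4 kept their call and 84 missed the threshold. With the brain marker score 2 kept it, 78 missed it and 8 reversed. The causes were not tested unless stated. DESeq2 called 2618, 3070 and, within 1.5 times, 5082 genes for P49 against P10, P90 against P49 and P90 against P10, and 648 at both steps (92 up at both, 60 down at both, 358 up then down, 138 down then up), which is another estimate of spread on the same counts. Fits of the 6 libraries of a comparison alone called 2134 for P49 against P10 and 35 for P90 against P49, where the P10 libraries, the closest to each other, no longer enter the spread. The brain marker score gave 1854, 56 and 543 genes and 6 and 9 lists for P90 against P49 and against P10, and P90 without libraries 7 and 9 gave 840 genes against P49. A minimum 2-fold change left 17 genes that fell and then rose. With an estimated correlation 0, 0 and 0 lists were called, and fry, which tests whether the members move 1 way on balance and does not compare with other genes, called 0 for P49 against P10 and 3 for P90 against P49. Leaving out 1 library gave 2 to 887, 204 to 2302 and 1217 to 4019 genes, 12 to 17, 10 to 16 and 13 to 17 lists, and 0 to 431 genes at both steps (0 to 104 up at both, 0 to 30 down at both, 0 to 227 up then down and 0 to 95 down then up). Without 1 ATAC library gains and losses were 2831 to 8776 and 4275 to 11331 at P49 against P10, 2161 to 8799 and 11393 to 17458 at P90 against P49, and 1267 to 8137 and 10448 to 21725 at P90 against P10. For H3K27ac they were 25980 to 49275 and 653 to 6310. The strongest peaks alone gave 1735 ATAC gains and 1600 losses at P49, 3326 gains and 3795 losses at P90 against P49, 2203 and 3170 against P10, and 1594 H3K27ac gains and 412 losses. A q below 1e-05 gave 871 and 438 ATAC gains at P90 and 118 H3K27ac losses, and peaks covering most of a region 350. A window of 100 kb left 2 of 12 ATAC tests near genes past the threshold. Reversed were the odds ratio of H3K27ac gains near genes that rose (0.725 with the strongest peaks) and the lists of cell cycle (0.898) and replication (0.904) at P90 against P49 without P49 library 4 (over left-out libraries 1.11e-06 to 0.898 and 6.34e-06 to 0.904). With the brain score the lists of cell cycle (0.668), brain neurons (0.626) and choroid plexus (0.219; 0.703 without libraries 7 and 9) reversed at P90 against P49, and those of brain neurons (0.723), choroid plexus (0.508) and hypoxia (0.81) against P10. With the brain score the log2 fold changes of Hpcal4 (−1.56), Mal2 (−0.45), Kcnj4 (−0.60), Camk2a (−1.36), Mef2c (−1.31; −0.18 without libraries 7 and 9), Nefl (−0.29), Stx1a (−0.29) and Egr3 (−0.49) reversed at P90 against P49, and those of Hpcal4 (−1.44), Nrgn (−0.12), Kcnj4 (−0.64), Mef2c (−1.70; −0.47 without libraries 7 and 9), Nefl (−0.56), Syn2 (−2.95; −1.29 without them), Elavl3 (−0.67), Gad2 (−1.76), Camk2a (−1.14), Gad1 (−2.69), Egr3 (−0.42) and Drp2 (−0.0253) at P90 against P10. The score is built from such transcripts. Genes under the count minimum at totals of 18979972 to 25760877 were not tested, and the depth of the peak lists is unknown.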

Other observations

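The tests in this part on chromosomes, brain transcripts and H3K27ac were chosen after the results had been seen. The gene lists had been planned. How the splits of libraries were to be read was set down after the results had been seen. Genes that mark blood and support cells changed with age. Of 7 erythroid genes 1 fell at P90 against P49, Hbb-bt by −3.45 (6 when adjusted over the list alone, camera adjusted p = 0.00443, adjusted p = 0.721 with an estimated correlation, 0.0593 without P90 library 8, 0.115 without libraries 7 and 9, 0.225 with the brain marker score), and all 7 fell against P10, Slc4a1 by −7.22 (camera adjusted p = 6.38e-05, adjusted p = 0.394 with an estimated correlation). Choroid plexus genes had none called by edgeR of 15 at P90 against P49 (3 lower at an unadjusted p below 0.05, 2 with DESeq2; camera adjusted p = 0.0266, adjusted p = 0.771 with an estimated correlation; 0.339, 0.16 and 0.145 without P49 library 6, P90 library 7 or P90 library 9) and 1 against P10, the water channel Aqp1 (−1.86; 0.00121, adjusted p = 0.479 with an estimated correlation, 0.464 without libraries 7 and 9). Their member Ttr was at 1328, 2491 and 4658 CPM in the P10 libraries, 4.54, 77.5 and 1653 at P49 and 0.684, 398 and 0.346 at P90. At P90 against P49 the endothelial list was higher (1 down, 3 up and 1 down when adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.721 with an estimated correlation, 0.0666 without P49 library 5, 0.0866 without P90 library 9, 0.703 without libraries 7 and 9 and 0.755 with the brain marker score). The cerebellar genes Gabra6 and Cbln3, chosen after their values were seen, were at 11.6 and 21.6 CPM in P49 library 5.

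Metabolic and ciliary genes changed in few members. Of 20 hypoxia and glycolysis genes Bnip3 fell at P49 (−0.91; list 0.236), Pfkp (1.61) and Adm (1.39) rose and Egln3 (−1.76) and P4ha1 (−1.14) fell at P90 against P49 (0.333), and against P10 Car9 rose by 2.15 and Pfkp by 2.35 and 4 fell, among them P4ha1 (−1.20) and Bnip3 (−1.08). There the list was lower, with a median of −0.37 and camera adjusted p = 0.0498 (adjusted p = 0.479 with an estimated correlation; 0.0556 and 0.0824 without P10 library 2 or 3, 0.174 and 0.082 without P90 library 7 or 9, 0.693 without both). Of 19 oxidative phosphorylation genes Sdha, on chromosome 13 with shifts of −0.50, −0.41 and −0.27 in the P90 libraries, fell by −0.89 at P90 against P49, and the list was not called (camera adjusted p = 0.235, 0.502 and 0.765 for P49 against P10, P90 against P49 and P90 against P10, the order kept in this paragraph). Of 22 cilia genes Tulp1 and Ift88 (−0.82, on chromosome 14 with its shifts of −0.33 to −0.21 at P90) fell and Nphp4 (0.86) rose at P90 against P49 (0.0432, adjusted p = 0.771 with an estimated correlation; 0.104, 0.201, 0.125 and 0.145 without P49 library 4 or 6 or P90 library 8 or 9; 0.309 with the brain marker score; 0.891 and 0.0972 in the other comparisons). Of 11 microRNA processing genes Ago1 fell by −0.57 at P90 against P49 and Ago1 (−0.91) and Tnrc6b (−0.51) against P10 (0.599, 0.168 and 0.112). The planned fry test put this list lower at P90 against P49 (fry adjusted p = 0.00377) and against P10 (0.00063). Dicer1, on chromosome 12 with its shifts of 0.37 to 0.62 at P90, stood at 0.57 ± 0.20 against P10. Not called were also WNT targets (0.149, 0.941 and 0.173; Lgr5 rose by 4.48 and Sp5 fell by −3.54 at P90 against P10), p53 targets at the single steps (0.531 and 0.566; Phlda3 rose by 1.86 at P49, and Plk2 rose by 2.16 and Perp fell by −2.32 at P90), lymphocyte markers (0.891, 0.941 and 0.765; Ptprc rose by 1.79 at P49), pericytes (0.447, 0.353 and 0.765; Cnn1 fell by −2.81 at P90 against P49) and Schwann cells (0.342, 0.422 and 0.243; Cdh19 rose by 2.67 at P49). Lists called at other steps missed the threshold for oligodendrocytes (0.728), brain neurons (0.976), fibroblasts (0.363), choroid plexus (0.105) and immediate early genes (0.647) at P49 against P10, for antigen presentation (0.0888), microglia (0.168) and astrocytes (0.333) at P90 against P49, and for circadian (0.983) and chromatin repressor genes (0.0877) at P90 against P10. The melatonin list, called at no step, had 0.765 at P90 against P10. Alternatives called some of these lists, with the preset correlation: antigen presentation was higher at P90 against P49 without libraries 7 and 9 (2.13e-06) and with the brain marker score (5.88e-08), and pericyte markers were lower there with that score (0.013). Without libraries 7 and 9, with library 8 alone at P90, lymphocyte markers were higher against P49 (0.0259) and P10 (0.00132) and cilia genes lower against P10 (0.038). Median, mean and test differed in sign for some uncalled lists: at P49 against P10 for oligodendrocytes (0.17, 0.34, lower), lymphocytes (−0.09, 0.36, higher) and cilia (−0.09, 0.05, lower). They also differed at P90 against P49 for WNT targets (0.10, −0.09, lower) and lymphocytes (−0.12, 0.28, lower), and at P90 against P10 for circadian (0.06, 0.24, lower), melatonin (−0.15, 0.07, lower) and chromatin repressor genes (−0.16, 0.03, lower).

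Transcripts of chromosome 12 genes and ATAC peaks on chromosome 12 were more frequent after P10: the median shift of 469 genes was 0.15 to 0.62 in the later RNA libraries, and the log2 share of ATAC peaks there against P10 was 0.52, 0.27, 1.14 and 0.85 in the 4 later libraries. The values argue against a few strongly changed genes, since at least 76.5% of its genes lay above their P10 level in each P90 library and in P49 libraries 5 and 6, but in P49 library 4 it was 60.8% and its genes called in no comparison had a median of −0.06, so this stays open there. They also argue against RNA of neighbouring brain as the whole cause, since P49 libraries 4 and 6, with brain marker scores no higher than at P10, had shifts of 0.15 and 0.35 against a bound of at most 0.09 from shuffled genes. A gain of the whole chromosome in part of the cells stays open: the lowest median of any of 3 parts of it in the P90 libraries was 0.33. A simulated gain of 1 copy in every cell, with no other chromosome changed, was recovered as 0.58. The RNA shifts of 0.60 and 0.62 in P49 library 5 and P90 library 9 are larger. In these libraries other chromosomes shifted too, such as chromosome 11 by 0.318 in library 5 and chromosome 8 by 0.349 in library 9. The ATAC values of 1.14 and 0.85 are shares of called peaks and not of copies, so they cannot be set against 0.58. An age effect on many chromosome 12 genes also stays open and untested, as mice without the transgene were not analysed here.

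Across 19 autosomes, which are not independent replicates, RNA shifts went with ATAC shares at P49 (Pearson r = 0.805, permutation p = 4e-05, adjusted 8e-05; Spearman rho = 0.763, permutation p = 0.00027, adjusted 0.00036) and at P90 (r = 0.803, permutation p = 2e-05, adjusted 8e-05; rho = 0.656, permutation p = 0.003, adjusted 0.003), with r = 0.58 and 0.625 without chromosomes 12 and 8. Chromosome 13 was lower at both later ages, with 21 genes called higher and 32 lower at P49 against P10 and 44 higher and 132 lower at P90 against P10. P90 library 8 had shifts of 0.52 on chromosome 8 and 0.51 on chromosome 18. Some chromosomes went against the correlation at P90. Chromosome 11 had RNA shifts of 0.221, 0.207 and 0.263 in libraries 7 to 9 and log2 ATAC shares of −0.164 and −0.155. The X chromosome, which was left out of the correlation, had −0.0775, −0.296 and −0.215 in RNA and 0.155 and 0.985 in ATAC.

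P90 libraries 7 and 9 held transcripts of neurons and oligodendrocytes. The median over 30 list members of the log2 ratio to library 8 was 1.93 and 1.53, which gives the size of the pattern and not its source, since these members had singled out the libraries (Sst and Tac2 were highest in library 8, at 33.3 and 4.19 CPM). Of the 30 members, 12 had a mean of at least 1 CPM at P10. Brain tissue next to the gland in those samples and, for their part of the transcripts, oligodendrocytes present in all samples of this age cannot be told apart, since only library 8 is left to judge by. Without libraries 7 and 9 the oligodendrocyte list had camera adjusted p = 0.00115, where the lone sample is assumed to vary like the other groups, and Mobp was at 6.92 CPM in library 8 while Camk2a was at 2.44.

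More H3K27ac regions were found at P90 than at P49. Weaker enrichment of the P49 ChIP libraries may account for part of it, since 17.2% of promoters open at both ages with unchanged expression carried a region of both P49 libraries (45.3% of replicate 1 and 23.2% of replicate 2, which differed) against 99.7% at P90. Acetylation gained where expression rose is argued against as the whole cause, because 48.4% of those promoters had a region at P90 alone. A wider true gain of the mark was not tested and stays open.

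For the counts of called genes, 3 libraries against 3 give 10 splits, too few for a share below 0.05. The real split was the 1 split with the most calls in each comparison. It gave 1124 genes against at most 1 for P49 against P10 and 1349 against at most 14 for P90 against P49. For P90 against P10 it gave 3488 against at most 0. Every other split mixes both ages within its groups, so any difference between the ages widens their spread and lowers their calls. The splits therefore cannot show how many of the called genes are right.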
